A study of Homo sapiens with 23 samples.

How the data were processed

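Gene expression was measured in HEK293T cells, a human embryonic kidney cell line, on 23 Affymetrix arrays of 54675 probe sets hybridized with biotin-labelled cRNA. Cells had received polyplexes of branched polyethylenimine and a plasmid with reporter genes for green fluorescent protein (GFP) and luciferase. The 23 arrays fall into 8 groups: treated (3 arrays) and untreated (2 arrays) cells at 2 h, and GFP-positive and GFP-negative cells, separated by flow cytometry, at 8, 16 and 24 h (3 arrays each). Per the labels' protocols, the 24 h RNA was extracted with Trizol alone, and the other RNA with Trizol followed by a column. One array titled as transfected, 8 h, replicate 3 has a source name that states 16 h; it was kept at 8 h, as its title and description state.

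The deposited values per array are log2 expression from RMA, per the submitters' processing notes, made with R 2.11.1 for the 2, 8 and 16 h arrays and with R 2.9.0 for the 24 h arrays. Of all 54675 probe sets, 0 had a value equal in all deposited digits in arrays of different times, whereas pairs of 2 h arrays shared between 7387 and 10353 such values. Array medians were 4.85 to 4.90 log2 units at 2 h, 4.66 to 4.71 at 8 h, 4.96 to 5.10 at 16 h and 4.93 to 4.97 at 24 h. They thus lay apart by time, except that transfected 16 h replicate 2 lay within the 24 h range. Each time therefore appears to have been normalized apart. For each time the authors also deposited a table with the mean log2 expression of each group, the log2 fold change and a posterior probability, which is a score from 0 to 1 of a model that is not named. A further column of the authors' deposited tables is headed as a fold change; it is a ratio in the 16 h table, and in the other tables it is a different quantity, the square of the log2 fold change, which was not used as a fold. The authors' deposited means equal the means of the arrays as labelled for all 54675 probe sets at 2, 8 and 16 h (tolerance 1e-06) and for 0 of them at 24 h. Values of the authors' deposited 24 h table are therefore given apart from values computed from the arrays as labelled.

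Probe sets were named from the symbols of the deposited tables, updated through the human reference annotation. Of 54675 probe sets, 41701 had exactly 1 gene symbol and 12974 had none. Of 64 probe sets whose symbol had been turned into a date by a spreadsheet, 58 were recovered. Of 20064 symbols in the tables, 16582 were current, 1847 were updated and 1635 were kept as given. For each gene the probe set with the highest mean over the 23 arrays was used, which gave 20030 genes.

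The following choices were made before the data were examined. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with all 23 arrays in 1 model, so that the 8 groups share 1 estimate of the spread. The contrasts were treated minus untreated at 2 h, GFP-positive minus GFP-negative at 8, 16 and 24 h, the mean of the last 3, and the differences between times. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 20030 genes, and error terms of log2 fold changes are standard errors (SE) of that fit. Across 26 gene lists (587 genes with repeats), camera of limma tested each list with a preset correlation between genes of 0.01, with a repeat at an estimated correlation and a repeat with fry. The lists cover heat shock proteins and co-chaperones, the unfolded protein response of the endoplasmic reticulum, the ATF4 integrated stress response, immediate early genes, interferon-stimulated genes, NF-kB and inflammatory genes, cytosolic nucleic acid sensors, NRF2 oxidative stress genes, metallothioneins, cholesterol synthesis, lysosome and autophagy, endocytosis, heparan sulfate proteoglycans, G2/M genes, G1/S genes, histones, p53 targets, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, hypoxia and glycolysis, actin and SRF targets, ion, amino acid and polyamine metabolism, and markers of haematopoietic, stromal and HEK293 cells.

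Genes were named by rule. In each main comparison these are the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes that passed and whose groups did not overlap, or the 10 smallest p where fewer than 5 genes passed. The 4 members with the smallest p of each list that passed were added, as were 15 fixed genes of stress, immediate early, inflammatory and cytoskeletal responses; differences between times name the 5 genes with the smallest adjusted p of each sign. Genes outside this rule, among them passing members of a list with 5 or fewer passing genes and genes named from the authors' deposited 24 h table, were chosen after their values were seen.

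On simulated data, 200 of 20030 genes were changed in normal noise with each gene's fitted spread and the layout of the 23 arrays. A log2 change of 1 was recovered in 93.3% of changed genes at 2 h, 98.3% at 8 h, 97.2% at 16 h and 100% at 24 h, and a log2 change of 0.5 in 46.0%, 42.9%, 48.7% and 61.7%. False calls numbered 14, 5, 9 and 11 genes at 2, 8, 16 and 24 h. No simulated array departed from its label, so these shares do not hold for genes whose spread the 24 h arrays raise. In the measured data, 64 genes at least 2-fold higher passed at 16 h without the 24 h arrays, and 6 with them. For these arrays, the number per group limits the precision.

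Other settings fixed at the same time were a model of the compared groups alone, the replicate number as a block, array weights, a trended and robust prior, the lower 40% of genes by mean left out, each probe set as its own feature, the mean of a gene's probe sets, probe sets with shared sequence left out, quantile normalization of the 23 arrays, centring on the median, a covariate for RNA quality from 3' and 5' control probe sets, a fold of at least 1.5, an adjusted p under 0.01, and each array left out in turn. Chosen after seeing the data were a model of the 17 arrays without the 24 h arrays, the naming rule repeated on that model, and the authors' posterior probability above 0.95 as the threshold. A comparison with p-values of the authors was planned and not run, since the authors' deposited tables hold posterior probabilities. Arrays were not regrouped by their values. Arrays of the same replicate number deviated together from their group means at 8 h (correlations 0.257, 0.290 and 0.350). The numbers were therefore taken to pair the 8 h populations, from the data and not from the labels. At 16 h the correlations were 0.243, 0.094 and 0.290, and at 24 h -0.115, -0.213 and -0.406. The main fit, fixed before, leaves this pairing out, and counts with the number as a block are given as an alternative. The other tools were the R package for data tables (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.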

Results

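Gene expression was profiled on 23 arrays in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, at 4 times after polyplexes had been added. Polyplexes are particles of a cationic polymer, here polyethylenimine, and plasmid DNA, here with a GFP and luciferase reporter. At 2 h, treated cells (n = 3 arrays) and untreated cells (n = 2) were measured without sorting. At 8, 16 and 24 h, GFP-positive cells (n = 3 per time) and GFP-negative cells (n = 3 per time) were sorted from treated cultures, so that both populations had met the polyplexes. Mean median log2 expression of the 8 groups lay between 4.68 and 5.08. The number of arrays per group limits the precision. Arrays are called biological replicates in the labels. The design text states that experiments were repeated on 3 days, but no label gives the day of an array. Nor do the labels state that each array is a separate culture, so the p-values measure the spread between these arrays alone.

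The 2 h comparison addresses which transcripts differ soon after contact with polyplexes. More genes fell than rose in treated cells: 30 were lower and 5 higher than in untreated cells, of 20030 genes tested. At an unadjusted p under 0.05 there were 1575. NEAT1, the long noncoding RNA that builds nuclear paraspeckles, fell from 9.88 ± 0.12 (SD, n = 2) to 8.87 ± 0.12 log2 units (SD, n = 3), a change of -1.002 log2 units (SE 0.17, adjusted p = 0.0161). IFIT5, an interferon-inducible RNA-binding protein, fell from 7.12 ± 0.16 to 5.98 ± 0.28 log2 units, a log2 fold change of -1.13 (SE 0.19, adjusted p = 0.0161). TRIM73, a member of the tripartite motif family, rose 2.56-fold (log2 1.36, SE 0.24, adjusted p = 0.0175). The other genes that rose were CALML4, SOCS7, MNT and PHF13, with log2 fold changes of 0.92, 0.63, 0.54 and 0.48. Among the genes that fell, LOC729088, LOC284926 and TTC30B changed by log2 -1.48, -1.35 and -1.14, and TRAM1L1, MCPH1, PLPP6 and KCTD18 by -0.97 to -0.93.

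Of the listed stress and inflammatory genes, IFIT5 alone passed over all genes at 2 h. FOS and EGR1, immediate early genes, had log2 fold changes of -1.65 (adjusted p = 0.344) and -1.95 (adjusted p = 0.427). Their untreated arrays spread by SD 2.55 and 2.51 log2 units. JUN was at log2 -0.28 (adjusted p = 0.634), HSPA1A at -0.71 (adjusted p = 0.505), IFIT1 at -0.43 (adjusted p = 0.616). ATF3, DDIT3 and CXCL8 were at -0.06, 0.06 and 0.11. Of 31 measured interferon-stimulated genes, 1 fell (IFIT5). Adjusted over the list alone, ISG15 (log2 0.65, SE 0.17) passed as higher and IFIT5 as lower. In other lists, NFKBIA (log2 0.44), the NRF2 partner MAFG (0.53), BBC3 of the p53 list (0.555) and NDST1 (0.53) passed as higher adjusted over the list alone. Of 26 lists, 0 passed in camera (2 at an unadjusted p under 0.05) and 0 in fry. The lowest adjusted p was 0.402, for the endocytosis list (median log2 fold change -0.09) and for haematopoietic markers (0.04). Without the 24 h arrays in the fit, 148 genes passed (42 higher and 106 lower), all 35 among them. The largest of these changes were DCAF4L1 (log2 1.72, SE 0.35, adjusted p = 0.0263) and ARRDC3, an arrestin-family gene (log2 -1.63, SE 0.29, adjusted p = 0.0129). Larger still were 2 RAP1A probe sets not kept for that gene, at log2 2.73 (SE 0.37) and 1.79 (SE 0.35). In a limma fit of all 54675 probe sets without the 24 h arrays their adjusted p values were 0.00498 and 0.0288, and with these arrays 0.866 and 0.981. A limma fit of the 2 h arrays alone gave 0 genes, the replicate number as a block 16, and array weights 930 (288 higher and 642 lower). The count rests on single arrays: 1 gene passed without untreated replicate 2, 4 without treated replicate 3 and 12 without treated replicate 2. In the control probe sets for ACTB, the 3' minus 5' difference was 2.68 log2 units in treated replicate 1 and 1.23 to 1.44 in the other 2 h arrays. The hybridization spike-in BioB read 8.09 log2 units in untreated replicate 2, on which the count rests, and 5.08 to 5.65 in the other 2 h arrays. For the spike-ins BioC, BioDn and CreX, untreated replicate 2 (9.39, 11.10 and 13.10) lay within the range of the other 2 h arrays.

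The 8 h comparison asks how cells that express the plasmid differ from cells that were exposed and do not. A group of genes with low levels in GFP-negative cells rose several-fold in GFP-positive cells. NEB, nebulin of the muscle sarcomere, rose from 3.51 ± 0.17 to 6.05 ± 0.10 log2 units (mean ± SD, n = 3 each). Its log2 fold change was 2.54 (SE 0.61, adjusted p = 0.0224). ACTA1, skeletal muscle alpha actin, rose from 4.65 ± 0.16 to 7.10 ± 0.25 (log2 fold change 2.45, SE 0.51, adjusted p = 0.0108). TPH1, tryptophan hydroxylase of serotonin synthesis, rose from 2.54 to 4.90 log2 units (SE 0.37, adjusted p = 0.00344). Detection calls were not used here. The GFP-negative level of TPH1 lies under the first quartile of those arrays (3.21 to 3.24) and those of NEB and ACTA1 under their medians (4.66 to 4.69), so the size of a change that begins this low is uncertain. CENPA, the histone H3 variant of centromeres, fell from 9.20 ± 0.06 to 8.04 ± 0.08, a log2 fold change of -1.17 (SE 0.12, adjusted p = 2.59e-05).

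In all, 978 genes passed at 8 h, 255 higher and 723 lower in GFP-positive cells. By at least 2-fold, 39 were higher and 8 lower. The balance depends on scaling: with quantile normalization of the 23 arrays 394 were higher and 535 lower, and with centring on the median 250 and 989. Among the highest were also the axonemal dynein gene DNAI4 (log2 2.81, SE 0.65, adjusted p = 0.018), GCNA (2.78), DCAF4L1 (2.09), LRRC23 (1.97), the cilia gene CFAP43 (1.90), LSMEM1 (1.85) and LOC387723 (1.84). For NEB, TPH1, DNAI4, CFAP43 and LRRC23, another probe set of the same gene changed by less than 0.5 log2 units at 8 and 16 h, while a further DNAI4 probe set rose by log2 1.55 and 1.77. The lowest included LOC100287616 (log2 -1.48), the neuroendocrine factor INSM1 (-1.18), the growth factor BMP2 (-1.14), HES4 (-1.13), the receptor EPHA3 (-1.10), PSRC1 (-1.04), the heparan sulfate epimerase GLCE (-1.03) and TAF6L (-0.99). ATF3 was at log2 1.46 (adjusted p = 0.144), DDIT3 at 1.12 (adjusted p = 0.145) and HSPA1A at 0.52 (adjusted p = 0.256). IFIT1 was at -0.56 (adjusted p = 0.0732) and CXCL8 at 0.08 (adjusted p = 0.739). RAP1A, a small GTPase, was at log2 0.15 on its brightest probe set (adjusted p = 0.445 over genes, and 0.518 in a limma fit of all 54675 probe sets). In the fit of all probe sets, 2 other RAP1A probe sets were at 4.61 (SE 1.53, adjusted p = 0.116, and 6.21e-07 without the 24 h arrays) and 4.77 (SE 1.63, adjusted p = 0.128, and 6.42e-07). Without the 24 h arrays in the fit, 2485 genes passed (827 higher and 1658 lower), all 978 among them. ATF3 and DDIT3 then had adjusted p = 0.000931 and 0.00442. With the replicate number as a block 475 genes passed, 98 higher and 377 lower, of which 417 were among the 978. Leaving out untransfected replicate 3 left 240 genes, transfected replicate 2 left 261, untransfected replicate 2 left 452, transfected replicate 1 left 549 and transfected replicate 3 left 594.

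**Figure D1:**
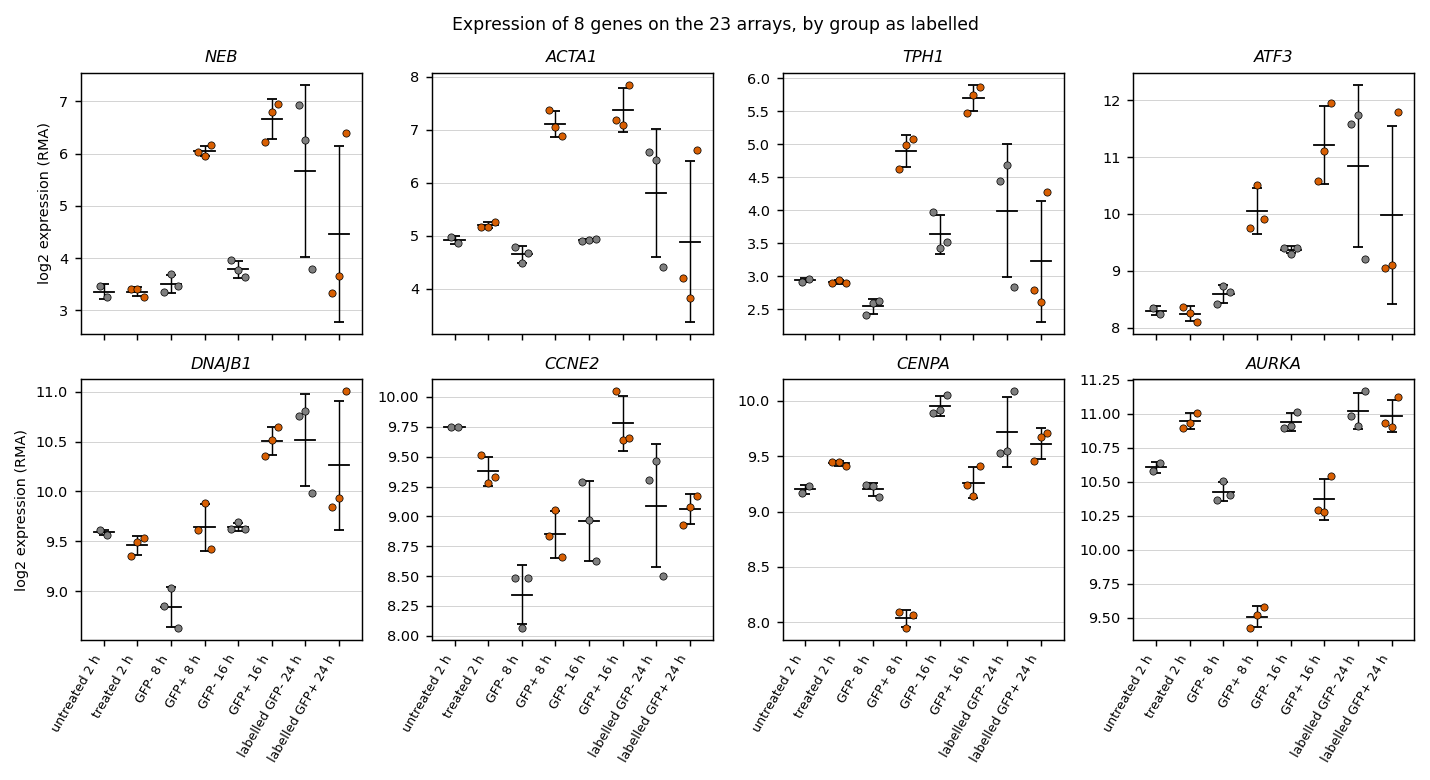
Log2 expression of 8 genes on each of the 23 arrays, by group as labelled; points are arrays, bars the group mean and whiskers its SD. NEB, ACTA1 and TPH1 are higher in every GFP-positive than in every GFP-negative array at 8 and 16 h, CENPA and AURKA are lower, and the 24 h arrays of each label spread over both levels for NEB, ACTA1, TPH1 and ATF3.

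Mitotic genes fell at 8 h as a group. Of 28 measured G2/M genes, 8 fell and 0 rose (median log2 fold change -0.32, camera adjusted p = 3.67e-10, and adjusted p = 0.0289 with an estimated correlation). The list did not pass with an estimated correlation when the 24 h arrays were left out (adjusted p = 0.299). Adjusted over the list alone, 17 fell and 1, PTTG1, rose. AURKA, a kinase of spindle assembly, fell by 0.92 on the log2 scale (SE 0.09, adjusted p = 2.59e-05). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell by 0.88 (SE 0.10, adjusted p = 0.000215), and KIF23, a kinesin of cytokinesis, fell by 0.72 (SE 0.13, adjusted p = 0.00476). The other genes that fell were AURKB, CDK1, TPX2 and CKS2. Heparan sulfate proteoglycan genes were lower as a group (20 measured, 0 passed and 0 adjusted over the list alone, median -0.22, adjusted p = 0.011, and adjusted p = 0.845 with an estimated correlation and 0.0666 with the lower 40% of genes left out). Their members included GPC2 at -0.37, EXT1 at -0.27, NDST2 at -0.52 and EXTL3 at -0.32. Cholesterol synthesis genes were lower likewise (24 measured, 0 passed and 0 adjusted over the list alone, median -0.16, adjusted p = 0.0438, and adjusted p = 0.845 with an estimated correlation and 0.202 with the lower 40% left out). INSIG1 was at -0.65, DHCR7 at -0.35 and SQLE at -0.33. The control signs of RNA quality were close between the populations, with a 3' minus 5' difference of 0.378 and 0.366 log2 units for GAPDH in GFP-positive and GFP-negative cells.

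Stress lists did not pass the list test at 8 h, although single members did. Of 27 heat shock genes, the co-chaperone DNAJB1 rose (log2 0.80, SE 0.23, adjusted p = 0.0471; list adjusted p = 0.0741, and 0 members adjusted over the list alone). Of 24 genes of the ATF4 response, DDIT4, an inhibitor of mTORC1, rose (log2 1.49, SE 0.25, adjusted p = 0.00358; list adjusted p = 0.0737). Of 14 histone genes, H2BC21 rose (log2 1.02, SE 0.25, adjusted p = 0.0219; list adjusted p = 0.0666). Without the 24 h arrays in the fit, these lists passed with camera adjusted p = 0.0127, 0.0127 and 0.00286 (adjusted p = 0.359, 0.835 and 0.359 with an estimated correlation), with 6, 5 and 4 members higher. In the hypoxia and glycolysis list NDRG1 (log2 -0.61) and ENO2 (-0.71) fell, and in the actin list ACTA1 rose and SRF (-0.37) fell. In the lysosome, endocytosis, NRF2, ribosome biogenesis, oxidative phosphorylation and ion transport lists UVRAG (-0.31), RAB5B (-0.74), MAFG (-0.41), RRS1 (-0.32), UQCRC1 (-0.54) and ATP2A2 (-0.50) fell. List adjusted p values were 0.0737 for lysosome and autophagy, 0.0985 for endocytosis and 0.991 for hypoxia and glycolysis. They were 0.856 for the actin, NRF2 and ion lists, 0.644 for ribosome biogenesis and 0.942 for oxidative phosphorylation. Lists with 0 members passing had 0.433 for the unfolded protein response, 0.472 for interferon-stimulated genes and 0.748 for NF-kB genes. They had 0.767 for nucleic acid sensors and ribosomal proteins, 0.288 for metallothioneins, 0.330 for G1/S genes and 0.874 for p53 targets. Immediate early genes (SRF passing) were at 0.748, HEK293 markers (ENO2 passing) at 0.767, and the markers of other cell types at 0.433 (haematopoietic) and 0.296 (stromal), each with 0 passing. Adjusted over the list alone, AKR1C2 (log2 0.33), H2BC9 (0.73), KDM3A (0.53) and SAT1 (1.09) also passed as higher and ALDOA (-0.30), CTSD (-0.375) and POLR1A (-0.35) as lower.

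The 16 h comparison asks the same of cells sorted later. TPH1 rose from 3.64 ± 0.29 to 5.70 ± 0.20 log2 units (mean ± SD, n = 3 each; SE of the change 0.37, adjusted p = 0.029). Its GFP-negative level lies under the first quartile of those arrays (3.70 to 3.75). LOC387723 (log2 1.49, SE 0.22, adjusted p = 0.023), the zinc finger genes ZNF596 (1.45) and ZFP2 (1.35), the receptor GPR83 (1.05), the cilia gene TTC21B (1.04) and TRIM66 (0.99) also rose. The mitotic genes CENPA (log2 -0.69, SE 0.12), KNSTRN (-0.71, SE 0.12) and AURKA (-0.57, SE 0.09) fell (adjusted p = 0.029 each). CCNB1, cyclin B1 (-0.53, SE 0.10, adjusted p = 0.04), fell too, as did SOS1, an exchange factor for Ras (-0.75, SE 0.13, adjusted p = 0.029).

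In all, 13 genes rose and 7 fell at 16 h, with 2878 genes at an unadjusted p under 0.05. Quantile normalization gave 44 higher and 9 lower, and centring on the median 44 and 7, so the count and its balance depend on scaling. The fit shares its spread with the 24 h arrays, whose values within a label differ widely for many of these genes. Without the 24 h arrays, 1266 genes passed (713 higher and 553 lower; 64 higher by at least 2-fold), the 20 genes among them. The largest changes in that fit were NEB (log2 2.87, SE 0.15, adjusted p = 6.42e-09, and 0.0625 with all 23 arrays), DNAI4 (log2 2.65, SE 0.21, adjusted p = 1.92e-06) and ACTA1 (2.45, SE 0.16, adjusted p = 1.06e-07). GCNA (2.44), the secretory granule gene SCG5 (2.15), TPH1 (2.06) and CFAP43 (2.02) followed. The lowest were SLC33A2 (log2 -0.93), SF3A2, SCRN2, PCED1A, MIB2, BMP2 (-0.84), MOGS and BCL2L2, a survival member of the BCL2 family (-0.80, SE 0.10, adjusted p = 0.00019). With all 23 arrays, 0 genes passed when any untransfected 16 h array was left out (n = 2 against 3) or with the replicate number as a block. There were 10, 3 and 2 without transfected replicates 1, 2 and 3, and 581 in a limma fit of the 16 h arrays alone.

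Stress-response genes were higher as groups at 16 h. For the ATF4 response (24 measured) the median log2 fold change was 0.39 (camera adjusted p = 7.05e-10, and adjusted p = 0.264 with an estimated correlation). Of its members, 0 passed over all genes, 8 rose adjusted over the list alone, and 10 were higher without the 24 h arrays. ATF3, a stress-induced transcription factor, was 3.59-fold higher (log2 1.84; adjusted p = 0.167 with 23 arrays and 0.000224 with 17), DDIT4 was at log2 1.23 (0.0515 and 0.000482) and CTH at 0.89 (0.141 and 0.00372), and SESN2 was at 0.76 (0.129 and 0.00362) and CEBPB at 0.46 (0.167 and 0.0247). For heat shock genes (27 measured) the median was 0.11 (adjusted p = 0.000343, and adjusted p = 0.336 with an estimated correlation). Of these, 0 passed over all genes and 3 rose adjusted over the list alone, DNAJB6 (log2 0.97), HSPA1A (0.89) and DNAJB1 (0.86). HSPH1 was at 0.48 and HSPA6 at 1.14. For histone genes (14 measured, 0 passing) the median was 0.29 (adjusted p = 0.000432, and adjusted p = 0.526 with an estimated correlation), with H2BC5 at 1.33 and H2BC9 at 0.46. For p53 targets (18 measured, 0 passing) it was 0.22 (adjusted p = 0.00101, and adjusted p = 0.526 with an estimated correlation), with PLK2 at 0.97, GADD45A at 0.74 and XPC at 0.33. The unfolded protein response (22 measured, 0 passing) had a median of 0.09 (adjusted p = 0.0127, and adjusted p = 0.519 with an estimated correlation), with DDIT3 at 1.07 (adjusted p = 0.278, and 0.01 without the 24 h arrays). In the histone, p53 and unfolded protein lists 0 members passed adjusted over the list alone.

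Cell cycle genes split at 16 h by phase. G2/M genes were lower: of 28 measured, 3 fell (CENPA, AURKA and CCNB1) and 0 rose, and 10 fell adjusted over the list alone. Their median was -0.24 (adjusted p = 1.27e-09, and adjusted p = 0.0205 with an estimated correlation, or 0.0858 with it and without the 24 h arrays). G1/S genes were higher: of 24 measured, 0 passed over all genes and 10 rose adjusted over the list alone. Their median was 0.18 (adjusted p = 6.93e-09, and adjusted p = 0.0203 with an estimated correlation, or 0.0858 with it and without the 24 h arrays). Neither list thus passed with an estimated correlation once the 24 h arrays were left out. CCNE2, cyclin E2, was at log2 0.82, MCM10 at 0.51, TK1 at 0.50 and CDC45 at 0.33. Cholesterol synthesis genes were lower (24 measured, 0 passing, median -0.14, adjusted p = 0.0127, and adjusted p = 0.526 with an estimated correlation). Ribosomal proteins were higher by a median of 0.03 (36 measured, 0 passing, adjusted p = 0.015, and adjusted p = 0.519 with an estimated correlation; 0.0558 without the 24 h arrays). Beside all these lists, the hybridization spike-in BioB read 5.89 ± 0.23 log2 units in GFP-positive and 8.07 ± 0.21 in GFP-negative arrays at 16 h (SD, n = 3 each), so this technical control differed with the populations at 16 h. At 8 h it read 5.25 and 5.09. The spike-ins BioC, BioDn and CreX were closer at 16 h, at 9.33 and 9.26, 11.36 and 11.14, and 13.07 and 13.10.

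The remaining lists did not pass at 16 h. Their adjusted p values were 0.0704 for immediate early genes, 0.608 for interferon-stimulated genes, 0.269 for NF-kB genes and 0.621 for nucleic acid sensors. They were 0.484 for NRF2 genes, 0.486 for metallothioneins and for lysosome and autophagy, and 0.206 for endocytosis. They were 0.321 for heparan sulfate proteoglycans, 0.332 for ribosome biogenesis, 0.199 for oxidative phosphorylation, and 0.551 for hypoxia and glycolysis, and 0.215 for actin and HEK293 markers, 0.547 for the ion and polyamine list, 0.414 for haematopoietic and 0.923 for stromal markers. Adjusted over the list alone, IFI27 (log2 0.65), P4HA1 (0.47), ACTA1 (2.45), SAT1 (1.31) and COL5A2 (0.88) of these lists passed as higher and ENO2 (-0.42), KRT19 (-0.54) and POLR1A (-0.38) as lower. HMOX1, a haem oxygenase of the NRF2 list, was at log2 1.05 (adjusted p = 0.272, and 0.041 without the 24 h arrays), and GDF15 at 0.60 (0.477 and 0.0389). IFIT1 (-0.39), CXCL8 (-0.11), JUN (0.22), FOS (0.32), EGR1 (-0.65), CDKN1A (0.25), MT1X (-0.12) and ACTC1 (0.15) passed in neither fit. Among lists that passed, the median, the mean and the test had the same sign; among the others they differed in 5 lists at 8 h and in 4 at 16 h.

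**Figure D2:**
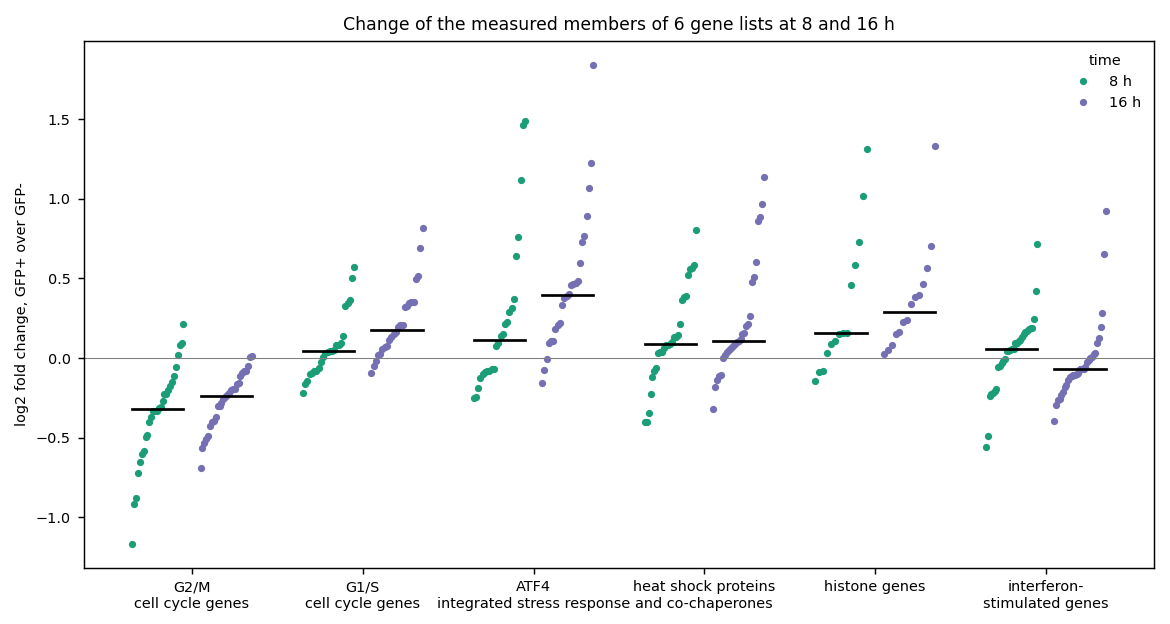
Log2 fold change, GFP-positive over GFP-negative, of each measured member of 6 gene lists at 8 and 16 h; points are genes and black lines medians. The G2/M medians are -0.32 and -0.24, and the ATF4 medians 0.12 and 0.39.

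The 24 h comparison asks the same of cells sorted at the last time. With the arrays as labelled, 0 genes passed in limma, and 1380 had an unadjusted p under 0.05. With array weights 1135 passed, and 873 passed when transfected replicate 3 was left out. The arrays within each label lay far apart: ATF3 read 9.98 ± 1.57 log2 units in the arrays labelled transfected and 10.85 ± 1.42 in those labelled untransfected (SD, n = 3 each; adjusted p = 0.75). The smallest p values belonged to H3C6 (log2 -0.95, SE 0.20), SASH3 (0.56), LOC285095 (0.36), LSAMP (0.45) and PHOX2A (0.49). The next were ACTG2 (0.45), SLITRK4 (0.31), C14orf93 (-0.48), RGS9 (0.31) and H2BC17 (-0.72, SE 0.18), none of which passed (adjusted p = 0.68 each). EGR1 was at log2 1.99 and CXCL8 at 0.32 (adjusted p = 0.709 each). Histone genes were lower in the arrays labelled transfected (median -0.50, camera adjusted p = 2.94e-09, and adjusted p = 0.711 with an estimated correlation). Of 14 members 0 passed, and 5 did adjusted over the list alone (among them H2AC6 at -0.99 and H2BC9 at -0.73). P53 targets (median -0.25, adjusted p = 3.09e-06, 0 of 18 passing) and the lysosome list (median -0.05, adjusted p = 0.0446, 0 of 27 passing, and adjusted p = 0.0544 with the replicate number as a block and 0.13 with the lower 40% left out) were lower too, each with adjusted p = 0.711 with an estimated correlation.

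The authors' deposited 24 h table holds other group means than these arrays as labelled, and its changes run largely the opposite way. Across 54675 probe sets, its log2 fold changes correlated with those of the arrays as labelled at r = -0.522, and at 2, 8 and 16 h at 1.0. In the authors' deposited 24 h table, which gives no error per gene, 596 genes were higher and 411 lower in GFP-positive cells at a posterior probability above 0.95, with 109 higher and 20 lower by at least 2-fold. On the probe set kept per gene, the highest in the authors' deposited table were DNAI4 (log2 2.96), NEB (2.57), SCG5 (2.48), GCNA (2.48), ATF3 (2.42) and ACTA1 (2.25). Some probe sets not kept were higher in the authors' deposited table, among them those of RAP1A (3.82 and 3.49) and CHORDC1 (3.31). The lowest in the authors' deposited table were SLC33A2 (-1.85), SF3A2 (-1.30) and PPOX (-1.28). In the authors' deposited 24 h table the ATF4 response had 12 of 24 members higher, among them DDIT3 (1.67), GDF15 (1.35) and CTH (1.12). Heat shock genes had 7 of 27 higher and 1, HSF1, lower in the authors' deposited table, with HSPA6 at 1.58 and DNAJB1 at 0.92. Histone genes and p53 targets had 6 of 14 and 6 of 18 higher in the authors' deposited table, among them H2BC5 (2.09), PLK2 (1.61) and GADD45A (1.12), and G2/M genes had 0 of 28 beyond 0.95 (median -0.05).

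**Figure D3:**
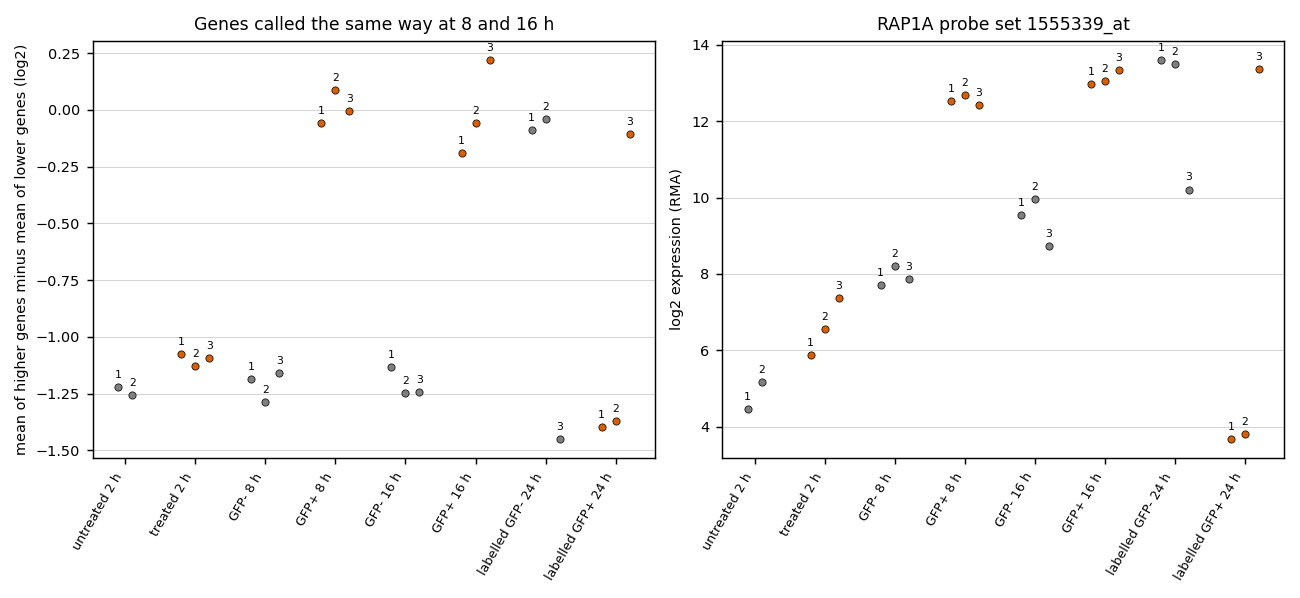
Left, mean log2 expression of genes higher in GFP-positive cells at 8 and 16 h minus that of genes lower at both times (739 genes), per array; right, log2 level of a RAP1A probe set that differs from the brightest of that gene, with points numbered by replicate. At 24 h, transfected replicate 3 and untransfected replicates 1 and 2 lie with the GFP-positive arrays of 8 and 16 h on both measures.

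The mean over 8, 16 and 24 h asks which genes differ in GFP-positive cells on average, which can rest on 1 or 2 of the times. With all 23 arrays as labelled, 125 genes were higher and 270 lower, of which 4 were higher by at least 2-fold. With quantile normalization 228 were higher and 196 lower, so the balance depends on scaling. At an unadjusted p under 0.05 there were 3397. The naming rule asked for groups that did not overlap at each time, 24 h included, where the labels are in doubt. It thus left out NEB and ACTA1, which passed for this mean in limma (adjusted p = 0.0431 and 0.0269) but whose labelled groups overlap at 24 h. Those higher at each time with the arrays as labelled, without a test of each time, included LINC00467 (log2 0.51, SE 0.11, adjusted p = 0.0209), ALDH7A1 (0.31), E2F2, an activator of S phase entry (0.31, SE 0.04, adjusted p = 0.00183), MSRB2 (0.28), BOK (0.26) and POLR3GL (0.22). Those lower at each time included ARAP2 (log2 -0.52, SE 0.07, adjusted p = 0.000696), GPR63 (-0.38), MSANTD2 (-0.37), TAF5 (-0.34), FUT4 (-0.31), NCBP3, a cap-binding protein (-0.29, SE 0.04, adjusted p = 0.00183), and KPNA2, an importin (-0.23). G2/M genes were lower (9 of 28 fell, 14 adjusted over the list alone, median -0.16, camera adjusted p = 8.14e-12, and adjusted p = 0.0152 with an estimated correlation). For the mean of 8 and 16 h without the 24 h arrays, the list did not pass with an estimated correlation (adjusted p = 0.137). CENPA was at -0.66 and AURKA at -0.51 (adjusted p = 4.8e-05 each), UBE2C at -0.39 and CCNB1 at -0.29. The ATF4 response (1 of 24 rose, DDIT4 at 0.89; 5 adjusted over the list alone; adjusted p = 2.08e-05), G1/S genes (0 passing, 4 adjusted over the list alone, adjusted p = 0.000833) and heat shock genes (0 passing, adjusted p = 0.024, and 0.0508 with the replicate number as a block) were higher. Cholesterol genes were lower (0 passing, 3 adjusted over the list alone, adjusted p = 0.0176, and 0.132 with the lower 40% left out). G1/S genes had adjusted p = 0.231 with an estimated correlation, and the other 3 lists adjusted p = 0.618 with an estimated correlation. For the mean of 8 and 16 h without the 24 h arrays, 3623 genes passed (1447 higher and 2176 lower), 388 of the 395 among them. The higher genes were led by DNAI4 (log2 2.73, SE 0.15, adjusted p = 4.63e-09), NEB (2.71, SE 0.10, adjusted p = 5.37e-11), GCNA (2.61, SE 0.18, adjusted p = 6.28e-08) and ACTA1 (2.45, SE 0.11, adjusted p = 1.79e-10), and the lower genes by SF3A2 (-1.01), BMP2 (-0.99) and CENPA (-0.93). ATF3 (1.65), DDIT4 (1.36), DDIT3 (1.09), DNAJB1 (0.83) and HSPA1A (0.70) rose and IFIT1 (-0.48, adjusted p = 0.0186) fell in that fit. The blocked count was 141 genes. Leaving out transfected 8 h replicates 1 and 2 gave 258 and 157 genes, untransfected 8 h replicates 2 and 3 gave 241 and 207, untransfected 16 h replicates 1 to 3 gave 215, 239 and 175, transfected 16 h replicates 2 and 3 gave 199 and 193, and, at 24 h, transfected replicate 1 gave 682 and untransfected replicates 2 and 3 gave 618 and 187.

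Differences between times were tested as such. Between 8 and 16 h, 0 genes differed in the size of their effect in limma (1497 at an unadjusted p under 0.05, and 0 under each alternative). There were 5 lists relatively higher at 16 h with 0 members passing. These were G1/S genes (median difference 0.14; TK1 at 0.59, UHRF1 at 0.43), endocytosis (0.10; RAB5B at 0.61, RAB7A at 0.55), and lysosome and autophagy (0.12; ATP6V0D1 at 0.45, CTSD at 0.41). The others were the ATF4 response (0.19; SLC3A2 at 0.59, NUPR1 at 0.56) and p53 targets (0.30; TP53INP1 at 0.65, BTG2 at 0.57). Camera adjusted p values were 0.00287 to 0.0104, and adjusted p = 0.484 to 0.656 with an estimated correlation. With the lower 40% of genes left out none of the 5 passed (adjusted p = 0.129 to 0.239). Between 16 h and the arrays as labelled at 24 h, LOC387723 passed (log2 -2.05, SE 0.31, adjusted p = 0.0333). Between 8 h and the arrays as labelled at 24 h, 24 genes were relatively higher and 26 lower. The higher included AURKA (0.88), UBE2C (0.95), CENPA (1.06), ZSCAN26 (1.01) and MOCS1 (1.19, and -0.041 with probe sets of shared sequence left out), and the lower LOC387723 (-2.41), TPH1 (-3.12), SNX31 (-1.22), RPL13P5 (-1.18) and ITGB1BP2 (-0.87). Without transfected 24 h replicate 3 or untransfected 24 h replicate 3, 2183 and 2065 genes passed for 24 against 16 h. For 24 against 8 h, 2201 and 2405 passed, and 1 to 12 without any other array; for 24 against 16 h, 4 passed without transfected 16 h replicate 1 and 0 without any other array. With the replicate number as a block, 0 passed in both.

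Effects at 8 and 16 h were correlated across genes. Log2 fold changes over 20030 genes correlated at r = 0.603 (Spearman rho 0.422), although genes are not independent replicates. At both times 15 genes passed, each with the same sign. Without the 24 h arrays in the fit, 395 genes were higher at both times, where 29.4 would fall together by chance, and 344 were lower at both, where 45.8 would. The 2 h effects correlated at 0.257 with those at 8 h and at 0.021 with those at 16 h. Effects of the arrays as labelled at 24 h correlated at -0.258 with 8 h and -0.446 with 16 h, whereas log2 fold changes of the authors' deposited 24 h table correlated at 0.617 with their 8 h table and 0.75 with their 16 h table.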

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

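The tests of labels and of normalization for the 24 h arrays, both tests of the RAP1A probe sets, and the splits within replicate numbers were chosen only after the result was seen.

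The arrays labelled 24 h stand apart from their labels. On the mean of 395 genes higher at 8 and 16 h minus that of 344 genes lower at both, 4 of the 6 arrays at 24 h lie on the far side of the 24 h mean. Quantile normalization of the 23 arrays left 4 there. Medians of the 24 h arrays were already close (4.93 to 4.97 log2 units), so this step could move the arrays little. It therefore does not decide on the authors' normalization. Of the 395 and 344 genes, 99.6% keep their 16 h sign in the authors' deposited 24 h table. This argues against an effect that turned round by 24 h. A candidate explanation is a mislabelled sample or several, since exchanged labels need arrays of both labels on the far side: relative to the 24 h mean, arrays labelled transfected 1, 2 and 3 read -0.65, -0.63 and 0.64, and arrays labelled untransfected 1, 2 and 3 read 0.65, 0.70 and -0.71. The authors' deposited GFP-positive mean is fitted by weights of 0.321 for transfected replicate 3 and 0.322 and 0.327 for untransfected replicates 1 and 2 (residual SD 0.0811). A simple exchange of labels would then give equal weights to the remaining arrays in the GFP-negative mean, and it does not: the weights are 0.0906 and 0.206 for transfected replicates 1 and 2, 0.559 for untransfected replicate 3, and 0.0902 and 0.0881 for untransfected replicates 1 and 2 (residual SD 0.121). The cause of the difference was not settled, so the groups were kept as labelled.

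Of the 4 RAP1A probe sets, 2 showed a signal that the gene's brightest probe set does not: log2 4.61 and 4.77 higher in GFP-positive cells at 8 h, and 3.72 and 3.51 at 16 h. Higher RAP1A expression as a whole is argued against, since the highest of the other probe sets reaches at most log2 0.392 (its change plus 2 SE). Whether a sequence shared with the plasmid could account for the signal stays open. Each array from cells given polyplexes at 2, 8 and 16 h lies at least 0.712 log2 units above the higher untreated array, as this explanation needs. At 24 h transfected replicates 1 and 2 would go against it only if they came from cells given polyplexes, as labelled. On the first probe set they read 3.68 and 3.81 log2 units, under both untreated arrays (4.46 and 5.17). The labels of these arrays are in doubt, so they do not decide it. An induced transcript of that locus stays open as well, because the plasmid and probe sequences were not used here.

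A probe set without a gene symbol was 3.00 log2 units higher in GFP-positive cells at 8 h and 2.91 at 16 h, in data that the comparisons of named genes leave out.

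Differences between times brought up further results, and each rests on a direct test of the difference. For 24 against 16 h, 1 gene passed, and for 24 against 8 h, 50 passed. For 16 against 8 h, adjusted p values of lists were 0.00287 for G1/S genes, 0.00502 for endocytosis, 0.00642 for the ATF4 response, 0.00642 for p53 targets and 0.0104 for lysosome and autophagy. For 24 against 16 h, they were 1.87e-08 for histones, 9e-07 for p53 targets, 3e-06 for G2/M genes, 6.28e-06 for the ATF4 response and 1.2e-05 for G1/S genes. In the same comparison they were 0.000641 for heat shock genes, 0.00315 for the unfolded protein response and 0.0383 for ribosomal proteins. For 24 against 8 h, they were 1.65e-08 for G2/M genes, 7.87e-07 for histones, 0.0112 for heparan sulfate proteoglycans, 0.0244 for heat shock genes, 0.036 for p53 targets and 0.0395 for cholesterol synthesis. With an estimated correlation 0 of these lists pass, and the differences from 24 h involve the arrays whose labels are in doubt.

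Other splits of the arrays were counted beside each gene count. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. At 8 h, 1 of 10 splits (the real one) gave 978 genes and the highest of the others 1, and at 16 h 1 of 10 gave 20 genes and the highest of the others 0. Without the 24 h arrays in the fit, 1 of 10 splits reached the real count at each time, 2485 against 1 at 8 h and 1266 against 5 at 16 h. At 24 h the real count is 0, which any split reaches (10 of 10), so the share says nothing about chance. The highest other split set transfected replicates 1 and 2 and untransfected replicate 3 against the other arrays and gave 3447 genes. None of the remaining splits gave more than 1. This points to a structure of the samples that the labels do not follow. For the mean over 8, 16 and 24 h, 1 of 100 splits within times reached 395 genes, with 58 the highest other, and for the mean of 8 and 16 h without the 24 h arrays 1 of 100 reached 3623, with 886 the highest other. These splits ignore that replicate numbers pair the 8 h arrays, so the groups were also exchanged within numbers, with the number as a block. At 8 h such splits are too few for a share under 0.05 (1 of 4 reached 475 genes, highest other 0). For the mean over 8, 16 and 24 h, 7 of 100 reached 141 genes, with 2650 the highest other, so chance cannot be excluded for it, and the high count again points to a structure that the 24 h labels do not follow. For the mean of 8 and 16 h without the 24 h arrays, 1 of 32 reached 4255 genes, with 0 the highest other. This share is under 0.05 and is the lowest that these splits can give, so chance is unlikely there but not excluded. The model and the splits were chosen after the result was seen, and the numbers were taken to pair arrays at 8 h alone. The splits also cannot part the GFP label from a technical difference that goes with it, as BioB does at 16 h. For 16 against 8 h the real count is 0 with and without the 24 h arrays, which any split reaches (100 of 100 each), so the share says nothing about chance (highest other 165, and 892 without the 24 h arrays). For the differences from 24 h chance cannot be excluded: for 24 against 16 h, 14 of 100 splits gave at least 1 gene (highest other 4563), and for 24 against 8 h, 14 of 100 gave at least 50 (highest other 4757). These splits also regroup the 24 h arrays, whose labels are in doubt, so their shares do not measure chance alone.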

How the results depend on the processing

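The tests without the 24 h arrays and with the authors' posterior probability were chosen only after the result was seen. Named genes were recomputed for changed samples, block, normalization and probe sets and with single arrays left out. Those past the threshold there or in the report kept their direction, except MOCS1 for 24 against 8 h, which went from log2 1.19 to -0.041 with probe sets of shared sequence left out. Genes past it in neither changed sign in 67 of all 4919 cases. The authors' deposited 24 h table is not among these settings and runs largely the opposite way. Across settings, results for named genes kept their side of the threshold in 281 of the cases at 2 h (73 weaker, 1 stronger), 506 at 8 h (68 weaker, 16 stronger), 644 at 16 h (115 weaker, 44 stronger), 411 at 24 h (24 stronger) and 1127 for the mean (64 weaker, 45 stronger). For 16 against 8 h they kept it in 371, for 24 against 16 h in 523 (11 weaker, 46 stronger) and for 24 against 8 h in 422 (104 weaker, 22 stronger). The count of genes for 16 against 8 h was 0 in each setting, and the settings of the whole set of arrays that are not named here kept total counts within 1.5 times. The comparison with p-values of the authors was not run.

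Leaving the 24 h arrays out raised the counts from 35 to 148 at 2 h, 978 to 2485 at 8 h, 20 to 1266 at 16 h and 395 to 3623 for the mean, where the 24 h effect left the contrast as well as the shared spread. Array weights gave 930 at 2 h, 1816 at 8 h, 1173 at 16 h, 1135 at 24 h (0 without them), 3402 for 24 against 16 h (1 without) and 3149 for 24 against 8 h (50 without). A fit of the compared groups alone gave 0 at 2 h, 581 at 16 h, 132 for the mean, and 0 for 24 against 16 and against 8 h. The replicate number as a block gave 16 at 2 h, 475 at 8 h, 0 at 16 h, 141 for the mean, and 0 for both differences from 24 h. The lower 40% of genes left out gave 6 at 16 h and 0 for 24 against 16 h. With each probe set on its own, counts were 107 at 2 h, 32 at 16 h, 836 for the mean, 0 for 24 against 16 h and 18 for 24 against 8 h. The mean of a gene's probe sets gave 17 for 24 against 8 h. Without probe sets of shared sequence, counts were 54 at 2 h and 23 for 24 against 8 h. Quantile normalization gave 53 at 16 h (44 higher and 9 lower, from 13 and 7), 394 higher and 535 lower at 8 h (from 255 and 723), 228 higher and 196 lower for the mean (from 125 and 270), 2 for 24 against 16 h and 109 for 24 against 8 h, and centring on the median 51 at 16 h (44 higher and 7 lower). A fold of at least 1.5 left 336 at 8 h and 23 for the mean. An adjusted p under 0.01 left 5 at 2 h, 186 at 8 h, 0 at 16 h, 26 for the mean, 0 for 24 against 16 h and 1 for 24 against 8 h. The authors' posterior probability above 0.95 gave 71 genes at 2 h, 572 at 8 h, 406 at 16 h and 1007 at 24 h. In the main test 39 list results passed. Counted over all lists, 4 passed with an estimated correlation, 8 with fry and 37 with the block, which changed no list call but those of heat shock for the mean and lysosome at 24 h. With the lower 40% of genes left out 33 list results passed, again counted over all lists, so they need not all be among the 39. Beside the losses given in the report, ribosomal proteins for 24 against 16 h (adjusted p = 0.125) and cholesterol synthesis for 24 against 8 h (0.142) no longer did. With the mean of a gene's probe sets 46 passed, without these same results (0.392 and 0.185). The correlation of 0.603 between 8 and 16 h was 0.691 without the lower 40%, 0.422 as Spearman's rho and 0.879 over genes that passed. Apart from settings that use fewer genes, fewer arrays or a stricter threshold, the cause was not tested.

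With single arrays left out, counts ranged from 1 to 51 at 2 h (1 without untreated replicate 2), 240 to 718 at 8 h (240 without untransfected replicate 3) and 0 to 10 at 16 h (0 without any untransfected array). They ranged from 0 to 873 at 24 h (873 without transfected replicate 3) and 157 to 682 for the mean, with the arrays named in the report. For 16 against 8 h they stayed at 0 to 0, for 24 against 16 h they ranged from 0 to 2183 and for 24 against 8 h from 1 to 2405 (2183 and 2201 without transfected, 2065 and 2405 without untransfected 24 h replicate 3), and the correlation from 0.54 to 0.651. Genes near the background level of the arrays limit what can be seen, since several of the largest changes at 8 h begin low, at 2.54 (TPH1) to 4.65 (ACTA1) log2 units.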

Other observations

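The naming of single probe sets in the next paragraph came only after the result was seen, whereas the tests of RNA quality and normalization for G2/M genes were chosen before.

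SAT1, the acetyltransferase that starts polyamine breakdown, was higher in GFP-positive cells, by log2 1.09 at 8 h and 1.31 at 16 h (adjusted p = 0.0569 and 0.0982), and passed at both times adjusted over its list alone. In the authors' deposited 24 h table SAT1 was at log2 1.27. Of 46 probe sets at least 2-fold higher at both times in genes with another probe set, 25 (24 genes) belong to genes whose brightest other probe set changed by less than 0.5 log2 units. In CHORDC1, a chaperone of the heat shock list, the changes were log2 2.00 and 3.23 against 0.03 and 0.08 on the brightest other probe set. PGAP1 (1.64 and 2.40 against 0.05 and -0.15) and the chromatin remodeller CHD2 (1.28 and 1.37 against -0.23 and -0.19) had the same split. Among 12912 probe sets without a symbol, 30 were at least 2-fold higher at both times.

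At 24 h, ATF3 and NEB differ between arrays of a label more than between labels. The RAP1A probe set in the plot of single arrays read 4.46 and 5.17 log2 units in untreated cells at 2 h, 5.88 to 7.36 in treated cells at 2 h, 7.72 to 8.20 in GFP-negative and 12.4 to 12.7 in GFP-positive cells at 8 h. In the arrays labelled transfected at 24 h it read 3.68, 3.81 and 13.4, and in those labelled untransfected 13.6, 13.5 and 10.2.

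Lower G2/M genes in GFP-positive cells were weighed as a pattern. The uncorrected median log2 fold changes of the list were -0.323 at 8 h and -0.237 at 16 h. With a covariate for RNA quality they were -0.324 and -0.239, and with quantile normalization of the 23 arrays -0.289 and -0.252. The covariate could move them little, since the 3' minus 5' difference was close between GFP-positive and GFP-negative cells. For GAPDH it was 0.378 and 0.366 log2 units at 8 h, and 0.15 and 0.10 at 16 h. This closeness argues against RNA quality, as these probe sets show it, as the whole cause. Quantiles already matched closely within a time, so quantile normalization does not decide on the authors' normalization. The BioB difference at 16 h was not tested as a cause. A difference in cell cycle between the sorted populations may remain, as a hypothesis: cells that divide and cells that do not could take up or express the plasmid unequally, or expression could change the cycle, and the design gives no test to part these.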
